A study of Mus musculus with 28 samples.

How the data were processed

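Gene counts were taken as deposited, 1 table per library, for 28 libraries of freshly sorted H2B-GFP mouse cells. The libraries covered thyroid gland at 3, 6 and 9 months and salivary gland at 9 months, each as a GFP+ and a GFP− fraction. Per the labels' protocols, RNA was isolated with a column kit and DNase treatment and converted to libraries with a 3′ mRNA sequencing kit. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq and the genome build was mm9, with no versions. The aligner and the counting program were not given in the sources used here. Groups followed the gland, GFP status and age in the labels. The replicates were not stated to be separate animals, so p-values measure only the spread between these samples.

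Each table held 47643 gene rows and 5 summary rows. The summary rows stayed out of library sizes and tests. Of all reads, 13.3 to 85.8% per library were outside genes (the no-feature row) and at most 0.426% were ambiguous. Gene identifiers were matched to symbols of a reference annotation (GENCODE vM21 names): 47224 matched and 419 did not, the latter holding at most 0.038% of reads in any library. Reads were seen in 17068 genes. Ribosomal RNA rows held 25.1 to 63.8% of the reads in genes and were kept. Mitochondrial messenger transcripts are among the gene lists. Among 36 pairs of libraries within groups, 0 were identical, and a chi-square per degree of freedom of at least 2.43 separated them.

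Depth was 507 to 209091 reads in genes. The limit for a gene with 0 reads was taken as 3 reads, the upper 95% bound of a Poisson count, which is 14.4 to 5920 CPM per library. Where 1 side of a comparison had 0 reads, the fold change is given as "at least", from 3 reads over the summed libraries of that group. With 1 to 3 reads the ratio of summed reads is given with its 95% interval. These intervals and limits cover counting error only. List medians are given as fitted, and also with such genes at their bounds where this moved them.

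Tests used edgeR 4.0.16 (R 4.3.3) with TMM factors (0.232 to 10.7), filterByExpr with its defaults (minimum 10, total 15), robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. All 22 thyroid libraries entered 1 fit of 6 groups, with 1900 genes tested and a biological coefficient of variation of 0.466. The 12 libraries at 9 months entered a second fit of 4 groups, with 974 genes and 0.48. Contrasts were GFP+ against GFP− at each age and as their mean, the interaction with age, age within each fraction (over all 3 ages and by pairs), the same sort in salivary gland, thyroid against salivary gland within each fraction, and the interaction with gland. Mean ± SD are over the libraries of a group, in CPM without TMM. Log2 fold changes are fitted values. A mean gives a shallow library the weight of a deep one: of 97 called gene results between groups, 55 had a mean that moved more than 1.5-fold without 1 library, 22 of them through a library with 1 to 3 reads of the gene.

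Of 47 marker and pathway lists, 28 had at least 3 tested members in the thyroid fit and 22 in the fit at 9 months. They were tested with camera (limma 3.58.1, preset correlation 0.01), with the correlation estimated per list, and with fry. Counts "adjusted over the list alone" apply the same adjustment to the list members only. Some genes mark more than 1 cell type, so a list is not proof of a cell.

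The tests, contrasts, lists, alternatives, and the rule for naming genes were fixed before the data were examined. The rule names, per comparison, up to 8 genes with the highest and up to 8 with the lowest fold change among called genes with a mean log2 CPM of at least 4 and no overlap between the libraries of the groups, leaving out predicted genes, pseudogenes and receptor segments. It also names up to 4 called members of each list described, by adjusted p, or the up to 2 most abundant where none was called, and a fixed set with Tg and Cdkn1a. Genes were dropped only from the low end of each ranking, apart from items not used here. The parathyroid genes given between 3 and 6 months are outside the rule.

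Alternatives were DESeq2 1.42.0, its size factors in the edgeR fit, no filter on low counts, a stricter filter of at least 20 counts in at least 50% of the libraries, all 28 libraries in 1 fit, only the groups compared, replicate numbers as a block, and leaving out each library in turn. Added after the data were seen were fits without libraries under 10000 reads and without ribosomal RNA rows. Whether replicate numbers pair the fractions was checked by correlating library residuals before the fits were compared. In thyroid, 3 of 11 same-number pairs had r above 0.1 (−0.089 to 0.351), in salivary gland 2 of 3, between glands 0 of 6 and between ages 0 of 10 in each fraction, so no block was used. Calls were also counted with group labels reshuffled, in up to 100 splits. The scripts were tested on simulated data with 200 changed genes. Of genes changed 4-fold, 17.9% were recovered at 3 months, 52.2% at 6 months and 35.8% at 9 months. Scripts used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.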

Results

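The series follows cells of the mouse thyroid gland that keep a histone H2B-GFP label, a mark that dividing cells dilute and slowly dividing cells retain. Cells were sorted fresh into a GFP+ and a GFP− fraction, and their polyadenylated RNA was profiled by 3′ mRNA sequencing. Thyroid glands were sampled at 3, 6 and 9 months, with 4, 4 and 3 libraries per fraction, and salivary glands at 9 months with 3 libraries per fraction. This gave 22 thyroid and 6 salivary libraries in 8 groups. The libraries were shallow and uneven. Reads assigned to genes ran from 507 to 209091 per library, 2263832 in all, and the genes detected from 121 to 10084. The GFP− thyroid groups held 27964 to 163544 reads per library at 3 months, 4845 to 209091 at 6 months and 5884 to 132610 at 9 months. The GFP+ thyroid groups held 1562 to 174957, 507 to 195513 and 65112 to 170230. Salivary libraries held 36095 to 188657 reads in the GFP− fraction and 993 to 79225 in the GFP+ fraction. Of the 201054 reads of the GFP+ thyroid group at 3 months, 174957 came from replicate 4. A transcript absent from a library could still have made up 14.4 to 5920 CPM (reads of a gene scaled to the library size), depending on the library, as the limit that 0 reads allow.

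**Figure D1:**
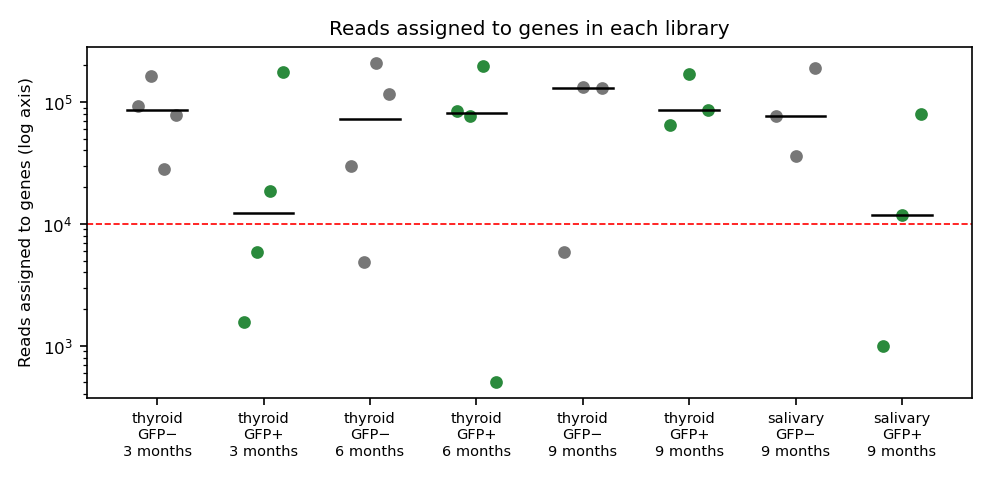
Reads assigned to genes in each of the 28 libraries on a log axis, grouped by gland, GFP fraction and age; points are libraries (green GFP+, grey GFP−), black bars are group medians and the dashed red line marks 10000 reads. The 6 libraries below the line held 507 to 5896 reads.

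The central comparison asked what distinguishes label-retaining from label-free thyroid cells, averaged over the 3 ages (n = 11 libraries per fraction). GFP+ libraries carried more transcripts of fibroblasts and fewer of blood vessels, C cells and red cells and of thyroid hormone synthesis genes. Of the 20 fibroblast genes tested, 19 were higher in the GFP+ fraction (19 when adjusted over the list alone), with a median log2 fold change of 1.87 against −0.08 for all genes tested. Biglycan (Bgn) rose from 30.6 ± 34.8 to 266 ± 193 CPM (mean ± SD; log2 fold change 3.08, adjusted p = 1.04e-09). Collagen gene Col1a1 rose from 65.7 ± 76.8 to 415 ± 300 CPM (2.46, adjusted p = 4.46e-08) and dermatopontin (Dpt) from 172 ± 126 to 922 ± 543 CPM (2.22, adjusted p = 2.26e-06). The receptor gene Pdgfra rose from 72.8 ± 68.1 to 276 ± 179 CPM (2.26, adjusted p = 2.58e-06). The fibroblast list stood above the other genes (camera adjusted p = 7.36e-17, adjusted p = 0.137 with an estimated correlation). In the same libraries 4 of 6 pericyte and smooth muscle genes were higher (5 when adjusted over the list alone). Smooth muscle actin Acta2 stood at a mean of 337 CPM against 89.3 ± 108 CPM (2.51, adjusted p = 4.69e-07) and the channel subunit gene Abcc9 at 135 ± 115 against 61.5 ± 70.7 CPM (1.72, adjusted p = 0.00105). The list test gave an adjusted p of 0.00216 (adjusted p = 0.285 with an estimated correlation).

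Endothelial genes moved the other way: 11 of 14 were lower in the GFP+ fraction (12 when adjusted over the list alone), with a median of −2.33 (camera adjusted p = 1e-15, adjusted p = 0.0248 with an estimated correlation). Esm1, an endothelial secreted proteoglycan, fell from a mean of 646 CPM to 5.72 ± 10.7 CPM (−6.72, adjusted p = 1.23e-23). The VEGF receptor genes Kdr (−4.85, adjusted p = 6.13e-18) and Flt1 (−3.31, adjusted p = 7.88e-11), the fenestral diaphragm gene Plvap (−4.08, adjusted p = 3.38e-16), Emcn (−3.44, adjusted p = 2.29e-12) and the lipid phosphatase gene Plpp1 (−3.68, adjusted p = 2.61e-13) fell with it. All 3 C cell genes were lower (3 when adjusted over the list alone, camera adjusted p = 8.22e-07, adjusted p = 0.0248 with an estimated correlation). Calca, which encodes calcitonin, fell from 1920 ± 882 to 251 ± 575 CPM (−4.65, adjusted p = 9.89e-16). That GFP+ mean was 79 CPM without replicate 4 at 6 months, where 1 read is 1970 CPM. The secretogranin gene Scg2 fell from 211 ± 141 to 6.26 ± 9.56 CPM (−5.35, adjusted p = 3.67e-17). The third, Chga, is also made by parathyroid cells (−1.56, adjusted p = 0.00925). All 4 globin genes were lower (4 when adjusted over the list alone, camera adjusted p = 3.08e-06, adjusted p = 0.13 with an estimated correlation). Hbb-bt (−2.78, adjusted p = 2.42e-07) and Hba-a2 (−3.64, adjusted p = 2.42e-08) have near-identical copies, so their separate values are uncertain. Without GFP+ replicate 4 at 3 months the value was −4.33 for Hbb-bt, −5.14 for Plpp1 and −5.83 for Plvap. Plpp1 was at −4.35 without GFP+ replicate 2 at 6 months, and Esm1 at −7.47 without GFP+ replicate 1 at 9 months. Chga lost its call without GFP− replicate 2 at 9 months (−1.36, adjusted p = 0.0716). Leaving out replicate 1 (−1.58, adjusted p = 0.0516), 2 (−1.56, adjusted p = 0.0613) or 3 (−1.56, adjusted p = 0.0551) of the GFP+ group at 9 months ended that call too.

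Thyroid hormone synthesis genes were lower in 4 of 5 cases (5 when adjusted over the list alone, camera adjusted p = 0.000893, adjusted p = 0.186 with an estimated correlation). Thyroglobulin (Tg), the hormone precursor, stood at 1560 ± 1250 CPM in the GFP+ and 4550 ± 2500 CPM in the GFP− fraction (−2.22, adjusted p = 8.66e-05). The deiodinase genes Iyd (−1.96, adjusted p = 2.66e-05) and Dio1 (−2.30, adjusted p = 0.000762) were lower as well. The list of thyroid transcription factors had 2 of 6 members tested, too few for a list test. Its pooled level was 496, 381 and 711 CPM in GFP− and 1060, 708 and 1120 CPM in GFP+ libraries at 3, 6 and 9 months. Zbtb20, singled out after its values were seen, held 105 of 180, 92 of 137 and 152 of 191 of these GFP− reads. It held 170 of 214, 234 of 253 and 349 of 359 in GFP+ libraries. Pooled Pax8 and Nkx2-1, on few reads, were lower in GFP+ at each age, and Foxe1 at 6 and 9 months. All 4 parathyroid genes were lower (4 when adjusted over the list alone, camera adjusted p = 0.00461, adjusted p = 0.323 with an estimated correlation). Parathyroid hormone (Pth) transcripts were abundant in both fractions, at 15200 ± 16900 CPM in GFP+ and 25800 ± 19300 CPM in GFP− libraries (−1.57, adjusted p = 0.00715). Kl, the klotho gene (−2.44, adjusted p = 2.64e-05), and the transcription factor gene Gata3 (−1.63, adjusted p = 0.00345) were lower too. Leaving out GFP− replicate 2 at 9 months ended the calls of Gata3 (−1.34, adjusted p = 0.0797) and Pth (−1.29, adjusted p = 0.0866). Pth also lost its call without GFP+ replicate 2 (−1.57, adjusted p = 0.0515) or 3 (−1.53, adjusted p = 0.0551) at 9 months. Without GFP+ replicate 4 at 3 months Gata3 stood at −2.78 and Kl at −3.06.

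Among signalling and stress lists, 9 of 12 inflammation and NF-kB genes were higher in GFP+ libraries (9 when adjusted over the list alone, camera adjusted p = 5.48e-07, adjusted p = 0.184 with an estimated correlation). The cytokine gene Il6 rose from 92.0 ± 127 to 254 ± 205 CPM (2.56, adjusted p = 2.82e-07) and the adhesion molecule gene Vcam1 from 28.9 ± 60.5 to 111 ± 97.7 CPM (3.06, adjusted p = 1.67e-06). The list of secreted senescence factors had 8 higher and 3 lower of 14 (9 and 3 when adjusted over the list alone, camera adjusted p = 0.0222, adjusted p = 0.577 with an estimated correlation). The chemokine gene Ccl7 was higher (2.42, adjusted p = 2.96e-06) and Igfbp3, an IGF binding protein gene, lower (−4.53, adjusted p = 6.13e-18). Of 13 TGF-beta and BMP genes 5 were higher (5 when adjusted over the list alone, camera adjusted p = 0.0141, adjusted p = 0.401 with an estimated correlation), among them Tgfbi (3.03, adjusted p = 1.94e-06). Without GFP+ replicate 4 at 3 months Tgfbi lost its call (2.31, adjusted p = 0.0739) and Igfbp3 stood at −6.17. Tgfbi was at 4.16 without GFP− replicate 3 at 6 months. Oxidative phosphorylation genes had a median of −0.49, with 1 of 33 called lower (0 when adjusted over the list alone, camera adjusted p = 0.00543, adjusted p = 0.635 with an estimated correlation).

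Other lists did not pass the camera test but held called genes. The quiescence and CDK inhibitor list had 1 of 9 genes called, Gas1, a growth arrest gene that was higher (1.69, adjusted p = 0.000303, list adjusted p = 0.841; 1 when adjusted over the list alone). Cdkn1a, the p21 gene, stood at 300 ± 212 CPM in GFP+ and 318 ± 227 CPM in GFP− libraries (−0.31, adjusted p = 0.681), and its sign changed with DESeq2 size factors (0.04). None of the 5 core histone genes was called, at a list adjusted p of 0.743. Of 8 stem and progenitor genes 2 were higher and 2 lower (2 and 2 when adjusted over the list alone, adjusted p = 0.841). Thy1, also a fibroblast surface marker, was higher (2.69, adjusted p = 1.04e-06) and Cd24a lower (−2.29, adjusted p = 8.62e-07; −4.60 without replicate 4 of the GFP+ group at 3 months). The median of that list was 0.06 although camera placed it below the other genes. The Wnt inhibitor gene Sfrp1 was higher (2.59, adjusted p = 0.000145) in a list with 3 of 7 called (3 when adjusted over the list alone, adjusted p = 0.384). Gpx3, a secreted glutathione peroxidase (2.62, adjusted p = 8.64e-08), was among 4 of 18 antioxidant genes that were higher (4 when adjusted over the list alone, adjusted p = 0.141). The receptor gene Axl (1.73, adjusted p = 0.000171) was among 2 of 8 Hippo targets (2 when adjusted over the list alone, adjusted p = 0.128). The imprinted noncoding RNAs Meg3 (2.50, adjusted p = 1.15e-05) and Kcnq1ot1 (1.84, adjusted p = 0.00301) were higher among 4 nuclear-retained RNAs (2 when adjusted over the list alone, adjusted p = 0.128). The interferon-induced Rsad2 was lower (−3.20, adjusted p = 1.7e-09) in a list with 1 higher and 2 lower of 7 (1 and 2 when adjusted over the list alone, adjusted p = 0.141). The small heat shock protein gene Hspb1 was lower (−1.45, adjusted p = 0.00555) among 3 of 9 heat shock genes (3 when adjusted over the list alone, adjusted p = 0.131). The Hspb1 call was lost without GFP− replicate 2 at 9 months (−1.26, adjusted p = 0.07). Its value was −2.78 without GFP+ replicate 4 at 3 months. Meg3 was at 3.28 and Kcnq1ot1 at 2.46 without GFP− replicates 3 and 4 at 6 months.

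Over all 1900 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 383 genes, 216 higher and 167 lower in GFP+ cells. Without GFP+ replicate 4 at 3 months, the split was 140 higher and 217 lower. With the replicate number as a block it was 93 and 95, and Abcc9, Chga, Pth, Gas1 and Axl lost their calls. Chga, Gata3, Pth and Hspb1 lost theirs without a filter on low counts, Chga, Gata3 and Hspb1 with DESeq2, Chga with DESeq2 size factors, and Chga and Pth with all 28 libraries in 1 fit. With DESeq2 size factors the median of all genes rose by 0.30 on the log2 scale, and 127 of 433 called genes were lower. In simulated counts of this design, 37.3% of genes changed 2-fold and 92.5% of those changed 4-fold were recovered.

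At 3 months (n = 4 per fraction) the GFP+ libraries held more fibroblast and contractile transcripts than the GFP− libraries. Of 20 fibroblast genes 12 were higher (18 when adjusted over the list alone, camera adjusted p = 4.04e-14, adjusted p = 0.193 with an estimated correlation), Col1a1 at 380 ± 348 against 33.8 ± 34.4 CPM (3.09, adjusted p = 0.000708). The transporter gene Abca8a was at 1320 ± 672 against 117 ± 51.3 CPM (2.86, adjusted p = 0.00242), and the fibrillin gene Fbn1 at 650 ± 280 against 50.3 ± 44.1 CPM (2.85, adjusted p = 0.00148). Of 6 pericyte and smooth muscle genes 3 were higher (5 when adjusted over the list alone, camera adjusted p = 5.5e-06, adjusted p = 0.123 with an estimated correlation). They included Acta2, at 486 ± 326 against 8.94 ± 6.03 CPM (5.02, adjusted p = 9.53e-07), and Myh11, the smooth muscle myosin gene (3.69, adjusted p = 0.00271). Without GFP+ replicate 4, Myh11 lost its call (3.22, adjusted p = 0.0575). Leaving out 1 library moved Abca8a to 2.24 (GFP+ replicate 3), Fbn1 to 3.48 (GFP− replicate 1) and Col1a1 to 3.72 (GFP− replicate 2) or 2.42 (GFP+ replicate 4). Inflammation and NF-kB genes were higher in 5 of 12 cases (6 when adjusted over the list alone, camera adjusted p = 3.71e-05, adjusted p = 0.258 with an estimated correlation). Airway epithelium genes summed to 761 ± 754 CPM in GFP+ and 136 ± 71.3 CPM in GFP− libraries, with most of the 322 GFP+ reads in replicate 4 (0 of 3 called, 2 higher when adjusted over the list alone, camera adjusted p = 0.04, adjusted p = 0.258 with an estimated correlation). Salivary acinar genes summed to 2220 ± 2460 and 385 ± 538 CPM (pooled 1260 and 347). Replicate 4 held 232 of the 253 GFP+ acinar reads but also 174957 of all 201054. The shallower libraries raised the GFP+ mean above the pooled level.

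On the lower side at 3 months stood 9 of 14 endothelial genes (13 when adjusted over the list alone, camera adjusted p = 7.67e-11, adjusted p = 0.0495 with an estimated correlation). Esm1 was at 894 ± 216 CPM in GFP− libraries and had 0 reads in GFP+ libraries, at least 63.9-fold lower against the limit of 3 reads over the group. Exoc3l2 (at least 11.1-fold) and Scg2 (at least 15-fold) also had 0 reads in GFP+ libraries, with adjusted p values of 0.000873 and 4.23e-05. Btnl9, at a mean of 721 CPM in GFP− libraries, had 1 read in GFP+ libraries (ratio of the summed reads 163, 95% counting interval 29.0 to 6460, adjusted p = 5.94e-08). Kdr fell from 2010 ± 512 to 58.8 ± 76.6 CPM (−5.04, adjusted p = 3.08e-06). All 3 C cell genes were lower (3 when adjusted over the list alone, camera adjusted p = 4.32e-05, adjusted p = 0.0727 with an estimated correlation), Calca falling from 1680 ± 543 to 29.1 ± 33.8 CPM (−5.34, adjusted p = 1.48e-05). The fitted median of that list was −5.34, and −3.90 with Scg2 at its bound. Tg was at 2140 ± 1110 CPM in GFP+ and 5200 ± 1060 CPM in GFP− libraries, a difference that did not pass (−1.91, adjusted p = 0.111). In all, 95 genes were called higher and 90 lower. The split changed with single libraries. It was 37 higher and 132 lower without GFP+ replicate 4. It was 58 and 73 without GFP+ replicate 3, and 63 and 74 without GFP− replicate 2. With the replicate block it was 9 and 36. Abca8a, Fbn1, Myh11 and Col1a1 lost their calls with that block and without a filter. With DESeq2 size factors, which raised the median of all genes by 0.61, the counts were 201 and 50. Without GFP+ replicate 4, the limits were at least 8.3-fold for Esm1, 1.94-fold for Scg2, 1.44-fold for Exoc3l2 and 7.05-fold for Btnl9, with Calca at −6.42.

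At 6 months (n = 4 per fraction) 11 of 20 fibroblast genes were higher in GFP+ libraries (17 when adjusted over the list alone, camera adjusted p = 5.69e-15, adjusted p = 0.148 with an estimated correlation). Bgn, with 3 reads in GFP− libraries (10.8 ± 15.8 CPM), was higher by a ratio of 42.9 over the summed reads (95% counting interval 14.3 to 211, adjusted p = 1.15e-05). Fibronectin (Fn1) was at 505 ± 407 against 51.7 ± 43.8 CPM (2.95, adjusted p = 0.0014) and vimentin (Vim), a mesenchymal intermediate filament, at 1270 ± 580 against 182 ± 160 CPM (2.84, adjusted p = 0.0033). Of the inflammation and NF-kB genes 4 of 12 were higher (8 when adjusted over the list alone, camera adjusted p = 1.5e-06, adjusted p = 0.163 with an estimated correlation), with Il6 at 283 ± 286 against 106 ± 205 CPM (4.24, adjusted p = 0.000143). That GFP− mean was 3.19 CPM without replicate 2, which held 2 of the reads. Pericyte and smooth muscle genes were higher in 4 of 6 cases (6 when adjusted over the list alone, camera adjusted p = 4.93e-05, adjusted p = 0.148 with an estimated correlation), Myh11 among them with 36 reads against 2 (ratio 18.1, 95% counting interval 4.66 to 155, adjusted p = 0.0125). Neuronatin (Nnat), a gene of endocrine cells, had 0 reads in GFP+ libraries (at least 37.1-fold lower, adjusted p = 1.19e-08), as did the adrenomedullin coreceptor gene Ramp3 (at least 8.62-fold lower, adjusted p = 0.000294). Endothelial genes were lower in 5 of 14 cases (6 when adjusted over the list alone, camera adjusted p = 2.87e-07, adjusted p = 0.128 with an estimated correlation). Esm1 fell from a mean of 561 CPM to 8.05 ± 9.96 CPM (−5.17, adjusted p = 1.2e-06), Kdr from 625 ± 377 to 24.3 ± 16.8 CPM (−4.41, adjusted p = 5.93e-05) and Podxl from 553 ± 379 to 36.5 ± 34 CPM (−3.69, adjusted p = 0.000176). Calca fell from 2110 ± 994 to 557 ± 944 CPM (85 CPM without the 1 read of GFP+ replicate 4; −4.68, adjusted p = 1.91e-05), 1 of 2 C cell genes called among 3 (2 when adjusted over the list alone, camera adjusted p = 5.46e-06, adjusted p = 0.0756 with an estimated correlation). All 4 globin genes were lower (4 when adjusted over the list alone, camera adjusted p = 9.07e-08, adjusted p = 0.0756 with an estimated correlation). Tg was at 1840 ± 1440 against 3550 ± 2420 CPM (−0.95, adjusted p = 0.631). The test called 100 genes higher and 35 lower. These were 46 and 32 without replicate 3 of the GFP− group, 46 and 36 without its replicate 4, 45 and 29 without replicate 2 of the GFP+ group and 106 and 55 without its replicate 3. With the replicate block they were 3 and 8. Vim, Kdr, Podxl, Fn1, Il6 and Myh11 lost their calls with that block and without a filter, Calca without a filter and Il6 with DESeq2. Myh11 lost its call without replicate 4 of the GFP− group (3.21, adjusted p = 0.109) or replicate 2 of the GFP+ group (3.36, adjusted p = 0.0619), and stood at 5.99 (summed reads at least 5.04-fold) without replicate 3 of the GFP− group. Without GFP+ replicate 3 the limits were 16.8-fold for Nnat and 3.91-fold for Ramp3, and Esm1 stood at −6.24. Il6 was at 5.27, 3.62 and 3.63 without GFP− replicates 2 and 4 and GFP+ replicate 2.

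At 9 months (n = 3 per fraction) endothelial genes were lower in GFP+ libraries in 8 of 14 cases (11 when adjusted over the list alone, camera adjusted p = 1.88e-21, adjusted p = 0.00564 with an estimated correlation). Plvap fell from 318 ± 145 to 11 ± 9.59 CPM (−4.77, adjusted p = 5.78e-05), Kdr from 587 ± 546 to 15.6 ± 18 CPM (−5.10, adjusted p = 5.48e-05) and the prolactin receptor gene Prlr from 526 ± 578 to 9.75 ± 8.96 CPM (−4.47, adjusted p = 0.00012). Esm1, at 431 ± 114 CPM in GFP− libraries, had 2 reads in GFP+ libraries (ratio 63.4, 95% counting interval 17.1 to 530, adjusted p = 2.36e-05). Thyroid hormone synthesis genes were lower in 4 of 5 cases (5 when adjusted over the list alone, camera adjusted p = 4.3e-10, adjusted p = 0.026 with an estimated correlation). Tg fell from 5020 ± 4190 to 411 ± 78.4 CPM (−3.79, adjusted p = 0.00842) and Iyd from 226 ± 201 to 17.6 ± 21.2 CPM (−3.70, adjusted p = 0.000523). The C cell list had 2 of 3 lower (2 when adjusted over the list alone, camera adjusted p = 3.03e-06, adjusted p = 0.0317 with an estimated correlation), Scg2 falling from 264 ± 229 to 11.7 ± 11.7 CPM (−4.48, adjusted p = 3.24e-05). No fibroblast gene was called (0 of 20 by edgeR, 0 when adjusted over the list alone), yet 19 of 20 fold changes were positive with a median of 1.25 (camera adjusted p = 1.3e-08, adjusted p = 0.321 with an estimated correlation). The inflammation and NF-kB list had 0 of 12 called (0 when adjusted over the list alone) and 12 positive fold changes (camera adjusted p = 0.000326, adjusted p = 0.321 with an estimated correlation). The keratin gene Krt6a was higher, at 753 ± 942 against 27.8 ± 30.4 CPM (4.02, adjusted p = 0.00388), the only called member of 5 in the basal and squamous epithelium list (5 when adjusted over the list alone, camera adjusted p = 0.0127, adjusted p = 0.482 with an estimated correlation). Bpifa1, an airway secretory gene, had 0 reads in GFP+ and 36 in GFP− libraries (at least 14.4-fold lower, adjusted p = 0.000848). Without GFP+ replicate 2 that limit was 6.75-fold, and without GFP− replicates 2 and 3 it was 3.15-fold and 24.7-fold. The Esm1 ratio was at least 33.7 without GFP+ replicate 1 and 29.8 without GFP+ replicate 2. Without GFP+ replicate 2, Plvap stood at −5.42, Prlr at −5.15, Iyd at −5.22, Kdr at −6.45 and Scg2 at −5.43. Krt6a was at 4.92 and 4.63 without GFP− replicate 2 and GFP+ replicate 3, and Kdr at −4.39 without GFP− replicate 2.

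Across the 1900 genes, 5 were called higher and 31 lower at 9 months, 169 at an unadjusted p under 0.05. DESeq2 size factors raised the median of all genes by 0.25. The split was 11 higher and 32 lower, 4 and 8, and 1 and 10 without GFP− replicates 1, 2 and 3. It was 0 and 6, 4 and 7, and 16 and 16 without GFP+ replicates 1, 2 and 3. With the replicate block it was 0 and 5, and Plvap, Iyd, Tg, Krt6a and Kdr lost their calls. Without a filter these and Esm1, Prlr, Bpifa1 and Scg2 did, with DESeq2 Iyd, Krt6a and Bpifa1, with DESeq2 size factors or without libraries under 10000 reads Krt6a, and with all 28 libraries Tg. Tg lost its call without any of replicates 2 (−3.68, adjusted p = 0.108) and 3 (−2.85, adjusted p = 0.33) of the GFP− group and replicates 1 (−3.87, adjusted p = 0.287), 2 (−3.65, adjusted p = 0.307) and 3 (−3.77, adjusted p = 0.189) of the GFP+ group. Iyd lost it without GFP− replicate 3 (−3.09, adjusted p = 0.101) or GFP+ replicate 1 (−3.27, adjusted p = 0.109). Krt6a lost it without GFP− replicate 3 (3.79, adjusted p = 0.0651) or GFP+ replicate 1 (2.50, adjusted p = 0.462), and Bpifa1 without GFP− replicate 2 (−4.21, adjusted p = 0.519) or GFP+ replicate 2 (−6.23, adjusted p = 0.0546). Esm1 lost it without GFP+ replicate 2 (−4.69, adjusted p = 0.0546) and Kdr without GFP+ replicate 1 (−4.67, adjusted p = 0.0608).

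**Figure D2:**
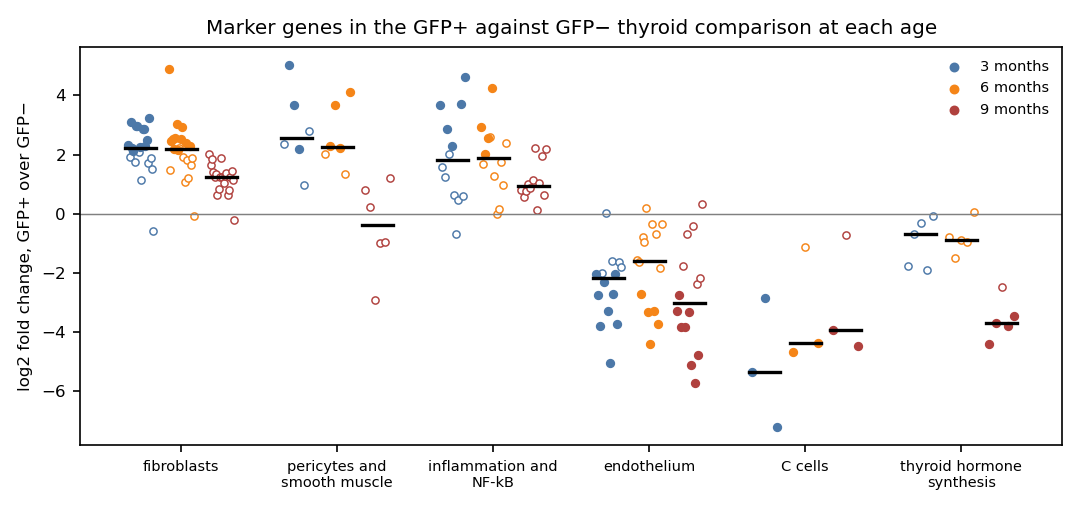
Log2 fold change of GFP+ over GFP− thyroid libraries for the tested members of 6 marker lists at 3, 6 and 9 months. Points are genes, filled where edgeR's adjusted p was under 0.05, and black bars are fitted list medians. Fibroblast medians were 2.24, 2.20 and 1.25, and endothelial −2.18, −1.60 and −3.01 (−2.93 with bounds).

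The calls at different ages overlapped. Genes called at both 3 and 6 months numbered 52 higher and 30 lower, where independent lists would share 5 and 1.66. At 3 and 9 months 0 higher and 24 lower were shared, against 0.25 and 1.47, and at 6 and 9 months 0 and 16, against 0.26 and 0.57. These comparisons share no libraries, only the fitted dispersion.

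Whether the GFP difference itself changed with age was tested by an interaction over the 3 ages, which called 3 of 1900 genes. Myh11 was higher in GFP+ libraries at 3 months (3.69) and 6 months (3.66), but at 9 months it was at 11 ± 9.59 CPM in GFP+ and 117 ± 50.6 CPM in GFP− libraries (−2.91, adjusted p = 0.121, interaction adjusted p = 0.000616). Calml3, an epithelial calmodulin-like gene, stood at 51.7 ± 76.0 and 20.1 ± 19.8 CPM in GFP+ libraries at 3 and 6 months and at 608 ± 745 CPM at 9 months (interaction adjusted p = 0.0021). Bpifa1 was at 114 ± 140 CPM in GFP+ libraries at 3 months and had 1 read at 6 and 0 reads at 9 months (interaction adjusted p = 0.000233). Between 3 and 9 months the pericyte and smooth muscle list fell relative to GFP− cells, with 2 of 6 genes called (4 when adjusted over the list alone, camera adjusted p = 1.32e-09, adjusted p = 0.0447 with an estimated correlation). The hormone synthesis list had 0 of 5 called (3 when adjusted over the list alone, camera adjusted p = 4.07e-05, adjusted p = 0.254 with an estimated correlation), and the fibroblast list 0 of 20 (0 when adjusted over the list alone, camera adjusted p = 0.000365, adjusted p = 0.73 with an estimated correlation). Beside these counts, 89 genes passed an unadjusted p under 0.05, DESeq2 called 0, and DESeq2 size factors moved the median of all genes by −0.37. Leaving out replicate 2 of the GFP− group at 9 months left 0 calls, ending those of Myh11 (−6.09, adjusted p = 0.109), Calml3 (4.46, adjusted p = 0.215) and Bpifa1 (−6.23, adjusted p = 0.178). Calml3 also lost its call without GFP− replicate 3 (4.49, adjusted p = 0.16) or GFP+ replicate 1 (2.84, adjusted p = 0.928) at 9 months, and Bpifa1 without GFP+ replicate 4 at 3 months (−5.76, adjusted p = 0.472). Calml3 lost it as well with the replicate block, without a filter, with DESeq2 size factors and without libraries under 10000 reads. The count was 6 without GFP− replicate 1 at 6 months or GFP+ replicate 2 at 3 months. It was 5 without GFP− replicate 2 at 6 months or, among GFP+ libraries, replicate 1 at 3 months, 3 at 6 months or 3 at 9 months.

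Among GFP+ thyroid cells, age was tested over all 3 time points and called 30 genes. Keratinocyte and squamous epithelial genes were higher at 9 than at 3 months: 4 of 5 list members were called (5 when adjusted over the list alone, camera adjusted p = 9.82e-05, adjusted p = 0.188 with an estimated correlation). The list summed to 14700, 2780 and 105 CPM in replicates 1 to 3 at 9 months, so replicate 3 stood near the earlier ages. Krt4 (1400 ± 1870 CPM at 9 months, at least 71.5-fold higher, adjusted p = 0.0209), Krt6a (753 ± 942 CPM, at least 40.3-fold, adjusted p = 0.000111) and stratifin Sfn (743 ± 1100 CPM, at least 34.8-fold, adjusted p = 2.93e-05) had 0 reads in the 4 GFP+ libraries at 3 months. Perp, a desmosome gene, rose from 14.3 ± 28.6 to 367 ± 522 CPM (3.15, adjusted p = 0.0348). The fitted median of the list was 8.81, and 5.33 with the genes at 0 reads at their bounds. Between 6 and 9 months 4 of 5 members were also higher (5 when adjusted over the list alone, camera adjusted p = 4.84e-10, adjusted p = 0.0464 with an estimated correlation). Hormone synthesis genes fell between 3 and 9 months, 2 of 5 called (5 when adjusted over the list alone, camera adjusted p = 5.27e-09, adjusted p = 0.0411 with an estimated correlation). Tg was at 411 ± 78.4 CPM at 9 and 2140 ± 1110 CPM at 3 months (−2.01, adjusted p = 0.48). Pericyte and smooth muscle genes fell in 2 of 6 cases (5 when adjusted over the list alone, camera adjusted p = 8.34e-08, adjusted p = 0.0411 with an estimated correlation), Myh11 from 152 ± 185 to 11 ± 9.59 CPM (−3.73, adjusted p = 0.0209). Endothelial genes had 0 of 14 called (5 lower when adjusted over the list alone, camera adjusted p = 1.86e-10, adjusted p = 0.0411 with an estimated correlation). Bpifa1 was at least 27.2-fold lower at 9 months (adjusted p = 0.000638), and globin genes were higher in 1 of 4 cases (4 when adjusted over the list alone, camera adjusted p = 5.38e-05, adjusted p = 0.172 with an estimated correlation).

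Between 3 and 6 months the parathyroid list rose in GFP+ libraries, 3 of 4 genes called (4 when adjusted over the list alone, camera adjusted p = 1.49e-09, adjusted p = 0.061 with an estimated correlation). The parathyroid genes given for this pair of ages were chosen after their values were seen. Pth rose from 4090 ± 1710 to 29800 ± 21700 CPM (3.43, adjusted p = 0.011), Gata3 from 5.72 ± 11.4 to 188 ± 213 CPM (3.85, adjusted p = 0.011) and Chga from 1650 ± 949 to 8570 ± 8930 CPM (3.29, adjusted p = 0.0288). Kl had 117 reads at 6 months and 1 at 3 months (ratio 65.8, 95% counting interval 11.6 to 2620, adjusted p = 0.00168). Without replicate 3 of the GFP+ group at 6 months, 0 genes were called between 3 and 6 months, with Pth at 2.19 (adjusted p = 0.903), Chga at 2.17 (adjusted p = 0.903), Gata3 at 2.70 (adjusted p = 0.903) and Kl at 4.29 (adjusted p = 0.335). Replicate 4 of the GFP+ group at 3 months also carried all 4 calls. Without it Pth stood at 3.46 (adjusted p = 0.0568). Chga (3.34) and Gata3 and Kl (0 reads at 3 months) had an adjusted p of 0.0918. Pth and Chga further lost theirs without replicate 2 of that group (3.27, adjusted p = 0.0555, and 3.04, adjusted p = 0.0697). The Kl ratio was 27.3 without replicate 3 at 6 months and at least 2.85 without replicate 4 at 3 months, and Chga stood at 3.89 without replicate 3 at 3 months. The endothelial list had a median of −0.84 for this pair of ages (0 of 14 called, 0 when adjusted over the list alone, camera adjusted p = 0.00017, adjusted p = 0.318 with an estimated correlation). Between 6 and 9 months the parathyroid median was −1.51 (0 of 4 called, 2 lower when adjusted over the list alone, camera adjusted p = 5.92e-05, adjusted p = 0.189 with an estimated correlation).

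Over the 3 ages, the 30 calls among GFP+ libraries were 13 without replicate 3 at 6 months and 48 without replicate 3 at 9 months, and DESeq2 called 0. Between 3 and 9 months 12 genes were called higher and 6 lower. With DESeq2 size factors, which moved the median of all genes by −0.23, the counts were 3 and 12. Between 3 and 6 months the counts were 12 and 2, and 5 and 5 with that scaling (median shift −0.45). Between 6 and 9 months they were 9 and 0 (median shift 0.22). The 18 calls between 3 and 9 months were 10 without replicate 4 at 3 months and 7 without replicate 1 at 9 months, where Perp stood at 1.16 (adjusted p = 0.943) and Sfn lost its call (adjusted p = 0.0572). Without that library the limits were 29.6-fold for Krt4, 19.6-fold for Krt6a and 9.42-fold for Sfn. Without replicate 4 at 3 months they were 9.29-fold, 5.22-fold and 4.52-fold, and 4.1-fold for Bpifa1. Without replicate 2 at 9 months they were 58.5-fold for Sfn and 12.8-fold for Bpifa1, and without replicate 3 at 9 months Perp stood at 3.77. Without replicate 4 at 3 months the calls of Krt4, Krt6a and Sfn (adjusted p = 0.134, 0.0879 and 0.0634) were lost. So were those of Perp (0 reads left at 3 months, adjusted p = 0.077), Myh11 (−3.33, adjusted p = 0.131) and Bpifa1 (adjusted p = 0.314). Krt4 and Perp also lost theirs without replicate 1 at 3 months (adjusted p = 0.155 and 0.0822) or replicate 2 (adjusted p = 0.246 and 0.0873), and Perp without replicate 3 (adjusted p = 0.169). Between 3 and 9 months all 6 named calls were lost with DESeq2, those of Krt4, Krt6a, Sfn and Perp with DESeq2 size factors or without libraries under 10000 reads, those of Krt6a, Perp and Myh11 with the replicate block, those of Perp and Myh11 without a filter, and that of Myh11 with all 28 libraries. Between 3 and 6 months all 4 were lost with DESeq2 and without a filter, those of Pth, Chga and Gata3 with the block or without libraries under 10000 reads, and those of Pth and Chga with DESeq2 size factors, all 28 libraries or only the groups compared. Myh11 lost its call without replicate 3 at 3 months (adjusted p = 0.138) or any of replicates 1 (adjusted p = 0.143), 2 (adjusted p = 0.121) and 3 (adjusted p = 0.16) at 9 months. The 9 calls between 6 and 9 months were 2, 16 and 25 without replicates 1, 2 and 3 at 9 months, and the 14 between 3 and 6 months were 7 and 2 without replicates 2 and 4 at 3 months and 22 without replicate 4 at 6 months.

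Among GFP− thyroid cells the test over age called 29 genes. Between 3 and 9 months 1 of 20 fibroblast genes was called higher (9 when adjusted over the list alone) and the median rose by 1.41 (camera adjusted p = 1.44e-10, adjusted p = 0.368 with an estimated correlation). The called member was Col6a2, a collagen gene that rose from 24.1 ± 17.8 to 222 ± 46.8 CPM (2.85, adjusted p = 0.0395). Abca8b, a lipid transporter gene, had 0 reads at 3 months and 254 ± 223 CPM at 9 months (at least 16.2-fold higher, adjusted p = 0.000192), or at least 8.9-fold without replicate 2 at 3 months. Endothelial genes had negative fold changes in 14 of 14 cases between 3 and 6 months, with 0 called (5 lower when adjusted over the list alone, camera adjusted p = 8.57e-12, adjusted p = 0.0277 with an estimated correlation), and 0 called between 3 and 9 months (0 when adjusted over the list alone, camera adjusted p = 4.76e-09, adjusted p = 0.114 with an estimated correlation). The parathyroid list had 0 of 4 called between 3 and 6 months (4 higher when adjusted over the list alone, camera adjusted p = 1.56e-05, adjusted p = 0.128 with an estimated correlation). Pth was at 15100 ± 6320 and 41400 ± 23100 CPM at these ages (1.54, adjusted p = 0.467) and Chga at 5970 ± 2570 and 16200 ± 10900 CPM (1.58, adjusted p = 0.464). Between 6 and 9 months the parathyroid median was −1.67 (0 of 4 called, 2 lower when adjusted over the list alone, camera adjusted p = 8.17e-05, adjusted p = 0.472 with an estimated correlation), and all 20 fibroblast fold changes were positive with a median of 1.13 (0 called, 0 when adjusted over the list alone, camera adjusted p = 3.4e-07, adjusted p = 0.534 with an estimated correlation). The squamous list had 0 of 5 called between 3 and 9 months (2 higher when adjusted over the list alone, camera adjusted p = 0.000424, adjusted p = 0.368 with an estimated correlation).

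The 29 calls over age in GFP− libraries were 1, 11 and 2 without replicates 1, 2 and 4 at 3 months, 49, 7 and 1 without replicates 2, 3 and 4 at 6 months, and 19, 3 and 2 without replicates 1, 2 and 3 at 9 months. By pairs of ages, 2 genes were higher and 1 lower at 6 than at 3 months, and 13 were higher and 0 lower at 9 than at 3 months. Between 6 and 9 months edgeR called 0 and DESeq2 0, with 156 at an unadjusted p under 0.05. The 13 calls were 1, 3, 8 and 1 without replicates 1 to 4 at 3 months, and 8, 2 and 1 without replicates 1 to 3 at 9 months. The 3 calls between 3 and 6 months were 0 without any 1 library at 3 months or replicate 3 or 4 at 6 months, 14 without replicate 1 and 21 without replicate 2 at 6 months. The 0 calls between 6 and 9 months were 2 and 10 without replicates 1 and 2 at 6 months, and 1 without replicate 1 at 9 months. DESeq2 called 2 over all ages, and DESeq2 size factors raised the medians of all genes by 0.14 between 3 and 6 months and by 0.13 between 3 and 9 months. Col6a2 lost its call without any of replicates 1 (2.77, adjusted p = 0.14), 2 (2.99, adjusted p = 0.154), 3 (2.70, adjusted p = 0.0737) and 4 (3.00, adjusted p = 0.0972) at 3 months or replicates 2 (2.82, adjusted p = 0.313) and 3 (2.61, adjusted p = 0.46) at 9 months. It also lost it with the replicate block, without a filter, with DESeq2 and with all 28 libraries.

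**Figure D3:**
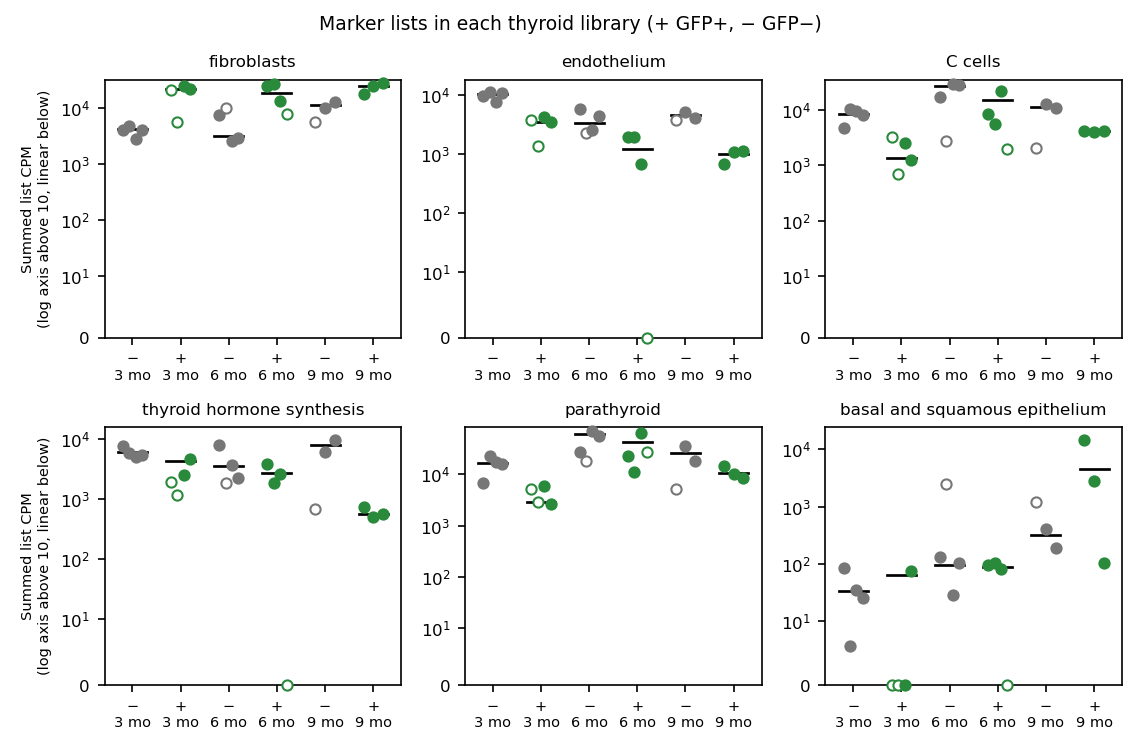
Summed CPM of 6 marker lists in each thyroid library by GFP fraction and age, on an axis that is linear below 10 CPM and logarithmic above; points are libraries (green GFP+, grey GFP−, open below 10000 reads) and black bars the pooled CPM of the group. Pooled fibroblast levels were 21700, 18900 and 24500 CPM in GFP+ and 4270, 3230 and 11500 CPM in GFP− groups at 3, 6 and 9 months. Chga, also made by parathyroid cells, held most reads of the C cell list in every thyroid group.

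The same sort was applied to salivary glands at 9 months (n = 3 per fraction), where no gene passed. Mitochondrial transcripts made up 19.7 ± 1.36% of the reads in GFP+ and 10.1 ± 4.93% in GFP− libraries, and reads outside genes made up 45.3 ± 21.5% and 17.2 ± 5.2% of the counted reads. Duct genes were lower in GFP+ libraries as a list (0 of 9 called, 7 lower when adjusted over the list alone, camera adjusted p = 1.36e-08, adjusted p = 0.383 with an estimated correlation), with a median of −2.63 against −0.89 for all genes. Acinar genes had a median of −1.69 (camera adjusted p = 9.27e-06, adjusted p = 0.708 with an estimated correlation). Ribosomal protein genes had −1.19, or −1.07 with bounds (camera adjusted p = 0.00282, adjusted p = 0.796 with an estimated correlation). Of these, 0 of 9 and 0 of 44 were called, and 0 when adjusted over the list alone. The secretory mucin-like gene Mucl2 was at 12800 ± 16300 CPM in GFP+ and 83200 ± 37700 CPM in GFP− libraries (−2.40, adjusted p = 0.586). The kallikrein gene Klk1 was at 3850 ± 1610 and 7140 ± 7690 CPM (−1.09, adjusted p = 0.796), its family members share sequence and it changed sign without replicate 3 of the GFP− group (0.23). Of 974 genes tested, edgeR called 0 and DESeq2 0, with 96 at an unadjusted p under 0.05. The count was 18 without GFP+ replicate 3, which held 79225 of the 92013 GFP+ reads, and 1 without GFP− replicate 2. In simulated counts of this design 77.3% of genes changed 8-fold and 25.4% of those changed 4-fold were recovered.

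The glands were compared within each fraction at 9 months (n = 3 per group), which also checks the labels. In GFP+ libraries all 9 acinar (9 when adjusted over the list alone, camera adjusted p = 5.21e-19, adjusted p = 0.0748 with an estimated correlation) and all 9 duct genes (9 when adjusted over the list alone, camera adjusted p = 8.29e-23, adjusted p = 0.0748 with an estimated correlation) were lower in thyroid. Smgc, a mucin-like gene of the submandibular gland, and Klk1 had 0 reads in thyroid (at least 1060-fold and at least 489-fold lower, adjusted p = 1.57e-06 and 4.47e-06). Mucl2 had 2 reads in thyroid and 2561 in salivary gland (ratio 4470, 95% counting interval 1240 to 36900), and the annexin gene Anxa9 fell from 1080 ± 951 to 27.7 ± 20.5 CPM (−5.32, adjusted p = 6.9e-07). On the thyroid side, Pth (10700 ± 2830 CPM, at least 317-fold higher, adjusted p = 0.00113), Krt4 (at least 32.7-fold, adjusted p = 0.00282), Abca8a (1150 ± 438 CPM, at least 35.3-fold, adjusted p = 0.000712) and the hyaluronan synthase gene Has1 (mean 881 CPM, at least 29.6-fold, adjusted p = 0.00163) had 0 reads in salivary GFP+ libraries. Fibroblast genes were higher in thyroid in 16 of 18 cases (18 when adjusted over the list alone, camera adjusted p = 1.04e-06, adjusted p = 0.286 with an estimated correlation), Col1a2 at 1780 ± 270 CPM against 1 read (ratio 172, 95% counting interval 30.8 to 6810, adjusted p = 0.00276). Their fitted median was 6.69, and 3.68 with genes at 0 reads at their bounds. The corresponding medians were −8.19 and −4.54 for duct and −11.57 and −8.35 for acinar genes. Mitochondrially encoded transcripts were lower in thyroid in 4 of 6 cases (6 when adjusted over the list alone, camera adjusted p = 1.04e-06, adjusted p = 0.242 with an estimated correlation). Of 8 endothelial genes 1 was lower (2 when adjusted over the list alone, camera adjusted p = 0.0288, adjusted p = 0.171 with an estimated correlation). Tg was at 411 ± 78.4 CPM in thyroid with 0 reads in salivary gland (at least 11.8-fold, or 1.64-fold without salivary replicate 3, adjusted p = 0.0768).

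The test in GFP+ libraries called 91 genes higher and 49 lower in thyroid, with a median of all genes at 1.15. With DESeq2 size factors, which raised that median by 1.68, the counts were 672 and 39. The split was 61 and 65, 33 and 40, and 12 and 19 without salivary replicates 1, 2 and 3. It was 34 and 40, and 45 and 41 without thyroid replicates 2 and 3. Without salivary replicate 3 the calls of Krt4 (9.33, adjusted p = 0.0676) and Col1a2 (4.53, adjusted p = 0.0516) were lost, and without its replicate 2 Col1a2 stood at 9.74 (at least 50-fold). Without salivary replicate 3 the limits were 44-fold for Pth, 4.55-fold for Krt4, 4.91-fold for Abca8a, 4.11-fold for Has1 and 570-fold for Smgc, and the ratios 729 for Mucl2 and 23.9 for Col1a2. Without thyroid replicate 1 the Krt4 limit was 13.5-fold and the Mucl2 ratio 7130, and without thyroid replicate 2 the limits were 230-fold for Klk1 and 499-fold for Smgc and the Mucl2 ratio 2100. Anxa9 was at −4.71 and −6.03 without thyroid replicates 2 and 3, and at −4.29 without salivary replicate 2. Anxa9 and Col1a2 lost their calls without a filter, Anxa9 with all 28 libraries, and Krt4 with DESeq2 size factors, without libraries under 10000 reads or without ribosomal RNA rows.

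In GFP− libraries the 9 acinar genes (9 when adjusted over the list alone, camera adjusted p = 1.26e-19, adjusted p = 0.0489 with an estimated correlation) and the 9 duct genes (9 when adjusted over the list alone, camera adjusted p = 4.26e-25, adjusted p = 0.0396 with an estimated correlation) were again lower in thyroid. The secretoglobin gene Scgb2b27 (17300 ± 3910 CPM in salivary gland, at least 1360-fold lower in thyroid, adjusted p = 3.01e-07), the growth factor gene Egf (812 ± 393 CPM, at least 72.2-fold, adjusted p = 1.94e-09) and Klk1b3 (442 ± 144 CPM, at least 44.9-fold, uncertain because kallikrein copies share sequence, adjusted p = 1.28e-10) had 0 reads in thyroid. Mucl2 had 3 reads in thyroid and 19159 in salivary gland (ratio 5690, 95% counting interval 1950 to 27600). Calca, with 0 reads in salivary gland, was at 2000 ± 1330 CPM in thyroid (at least 271-fold higher, adjusted p = 2.32e-07). Tg was at 5020 ± 4190 against 59.9 ± 47.5 CPM (4.73, adjusted p = 0.00198) and Pth at 19200 ± 14900 against 49.5 ± 43.8 CPM (6.89, adjusted p = 0.00244). Fibroblast genes were higher in thyroid in 8 of 18 cases (11 when adjusted over the list alone, camera adjusted p = 8e-06, adjusted p = 0.454 with an estimated correlation), globin genes in 4 of 4 (4 when adjusted over the list alone, camera adjusted p = 0.000876, adjusted p = 0.284 with an estimated correlation) and endothelial genes in 1 of 8 (1 when adjusted over the list alone, camera adjusted p = 0.0186, adjusted p = 0.158 with an estimated correlation). Mitochondrially encoded transcripts had 0 of 6 called (5 lower when adjusted over the list alone, camera adjusted p = 0.00134, adjusted p = 0.454 with an estimated correlation). Fitted medians were −10.59 for duct, −13.04 for acinar and 2.93 for fibroblast genes, and −6.48, −9.95 and 2.62 with genes at 0 reads at their bounds.

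The test in GFP− libraries called 96 genes higher and 42 lower in thyroid, with a median of all genes at 0.17. With DESeq2 size factors, which raised it by 1.38, the counts were 466 and 32. The split was 149 and 54, 29 and 35, and 22 and 35 without thyroid replicates 1, 2 and 3. It was 41 and 41, and 1 and 31 without salivary replicates 2 and 3. Tg lost its call without salivary replicate 2 (4.89, adjusted p = 0.0514) or 3 (4.04, adjusted p = 0.159), and Pth without salivary replicate 3 (6.21, adjusted p = 0.0829). Tg also lost it without a filter. Tg was at 5.48, 4.08 and 5.99 without thyroid replicates 1 and 3 and salivary replicate 1. Pth was at 7.59, 6.30 and 7.93 without thyroid replicates 1 and 2 and salivary replicate 1. Without thyroid replicates 2 and 3 the limits were 691-fold and 703-fold for Scgb2b27, 36.6-fold and 37.2-fold for Egf, and 22.7-fold and 23.1-fold for Klk1b3. The Mucl2 ratio was at least 2880, then 2940 and 8800, without thyroid replicates 2 and 3 and salivary replicate 3, and the Calca limit 101-fold without salivary replicate 3.

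Whether the GFP difference differed between glands was tested by an interaction at 9 months. Endothelial genes had a median interaction of −1.59 against 0.95 for all genes, below what the salivary comparison would give (0 of 8 called, 2 lower when adjusted over the list alone, camera adjusted p = 1.15e-06, adjusted p = 0.0103 with an estimated correlation). Salivary GFP+ libraries held 38 reads of the endothelial list (3930 ± 6190 CPM), 11 of them in replicate 1 with its 993 reads. Ribosomal protein genes had a median of 1.59 (0 of 44 called, 0 when adjusted over the list alone, camera adjusted p = 2.41e-06, adjusted p = 0.831 with an estimated correlation). Of 974 genes, edgeR called 0 and DESeq2 0, with 86 at an unadjusted p under 0.05, and 1 called without GFP− thyroid replicate 1. DESeq2 size factors raised the median of all genes by 0.27, and in simulated counts 33.3% of genes with an 8-fold difference between glands were recovered.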

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

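All tests of explanations in this part were chosen only after the results were seen; only the counts over reshuffled groups were planned before.

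Some libraries lay far from the rest of their group. Reads outside genes made up 53% of the counted reads in GFP− thyroid replicate 2 at 6 months (others 17.3 to 18.2%). In GFP+ replicate 4 at 6 months they made up 85.8% (others 22.2 to 28.6%). Mitochondrial transcripts made up 6.34% in replicate 1 of the GFP− group at 6 months (others 3.34 to 3.72%). Squamous epithelial genes summed to 2480 CPM in replicate 2 of that group (others 28.7 to 134). GFP+ replicate 4 at 3 months held 175000 reads (others 1560 to 18600). It alone held reads of the squamous (74.3 CPM) and red cell (223 CPM) lists. The others had 0, with a limit of 115 CPM over the 3 together. The red cell level lay above that limit, while for the squamous list depth leaves open whether this library differs. These were 7 of 52 comparisons of a library with its group, and chance would mark 1 in 20.

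The test of whether the GFP difference varied with age called 3 genes: Bpifa1 (adjusted p = 0.000233), Myh11 (adjusted p = 0.000616) and Calml3 (adjusted p = 0.0021). Leaving out GFP− replicate 2 at 9 months ended all 3 calls, and 47 of 100 reshuffled splits called as many. By camera with its preset correlation, the lists that passed between 3 and 9 months were pericytes and smooth muscle (camera adjusted p = 1.32e-09; adjusted p = 0.0447 with an estimated correlation), thyroid hormone synthesis (4.07e-05; adjusted p = 0.254 with an estimated correlation) and fibroblasts (0.000365; adjusted p = 0.73 with an estimated correlation). The others were heat shock (0.00651; adjusted p = 0.73 with an estimated correlation), airway epithelium (0.0198; adjusted p = 0.256 with an estimated correlation), ribosomal proteins (0.0198; adjusted p = 0.788 with an estimated correlation), mitochondrially encoded genes (0.0225; adjusted p = 0.73 with an estimated correlation), immediate early genes (0.0369; adjusted p = 0.788 with an estimated correlation) and parathyroid genes (0.041; adjusted p = 0.73 with an estimated correlation). Between 3 and 6 months those that passed were interferon response (0.000181; adjusted p = 0.125 with an estimated correlation), airway epithelium (0.0131; adjusted p = 0.125 with an estimated correlation), and heat shock and mitochondrially encoded genes (0.0446 each; adjusted p = 0.932 with an estimated correlation). Without libraries under 10000 reads the parathyroid (0.167), airway (0.0939), heat shock (0.217), ribosomal (0.485), mitochondrially encoded (0.704) and immediate early (0.548, in the other direction) lists no longer passed between 3 and 9 months, nor did the airway (0.168), heat shock (0.479) and mitochondrially encoded (0.0956) lists between 3 and 6 months. Between glands the lists that passed were endothelium (1.15e-06; adjusted p = 0.0103 with an estimated correlation) and ribosomal proteins (2.41e-06; adjusted p = 0.831 with an estimated correlation).

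The higher fibroblast and lower endothelial genes of GFP+ thyroid libraries were weighed first. Shallow libraries were not the source: 29 of 34 tested members were called in the same direction without them. With DESeq2 size factors 30 of 34 were, so the scaling was not the source either. A smaller share of endothelial cells alone would raise the other cell types, but the C cell median was −4.65. A larger share of fibroblasts among GFP+ cells could produce the fibroblast part, as 18 of 20 members lay within 1 log2 unit of the list median, although this shape does not tell a share of cells from a common change in expression. Whether label retention differs between cell types or cell states was not tested.

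Parathyroid transcripts in thyroid libraries, highest at 6 months, were weighed next. Parathyroid cells collected with the thyroid could carry them: across 17 libraries of at least 10000 reads, Pth and the other parathyroid genes, each centred within group, had a Spearman correlation of 0.728 (p = 0.0014 from 100000 resamples). It was 0.607 without the 2 farthest libraries. The correlation shows that the genes rise and fall together, not how the cells came into the sample.

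The squamous genes of GFP+ libraries at 9 months were also weighed. Whether squamous tissue was collected at that age in both fractions stays open. The pooled level in GFP− libraries was 5.02 times that at 3 and 6 months (320 against 63.7 CPM). The ratio of means was only 1.65 (596 against 362 CPM). That 362 rests largely on replicate 2 at 6 months (2480 CPM in 4845 reads, others 28.7 to 134). In GFP+ libraries the pooled level was 55.7 times that at 3 and 6 months (4490 against 80.6 CPM), and 23.4 times without replicate 1 at 9 months (1890 CPM). Replicates 1 and 2 had 14700 and 2780 CPM, but replicate 3 only 105 CPM. A single library as the source could be neither shown nor excluded: 2 of the 4 calls remained without GFP+ replicate 1 at 9 months. Without libraries under 10000 reads, or with DESeq2 size factors, 0 of the 4 remained, so these calls depend on both. Only Perp had a measured fold (2.97 and 3.12 against 3.15).

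Reshuffled groups can make chance less likely but not exclude it. Only the real split called as many genes for the mean GFP difference (383 calls, highest other 114, 1 of 100 splits). So it was at 3 months (185, highest other 85, 1 of 35) and for age in GFP− cells (29, highest other 16, 1 of 100). For age in GFP+ cells 3 of 100 splits called 30 or more (highest other 154), under 1 in 20. Over 1 in 20 did at 6 months (135, highest other 159, 2 of 35) and for GFP by age (3, highest other 21, 47 of 100). Splits were too few at 9 months (36, highest other 31, 1 of 10) and between glands in GFP+ (140, highest other 32, 1 of 10) and GFP− cells (138, highest other 44, 1 of 10). With 0 calls, splits decide nothing for GFP by gland (highest other 135, 100 of 100) or salivary gland (highest other 0, 10 of 10).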

How the results depend on the processing

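Of the alternatives below, the fits without libraries under 10000 reads and without ribosomal RNA rows were tests chosen only after the results were seen. The planned minimum of 500000 reads left no library, so that alternative has no value. Unless stated, the cause was not tested.

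The 383 calls of the mean GFP difference were 89 with the stricter filter and 335 to 425 on leaving out 1 library. The 185 at 3 months were 22 without a filter, 49 with the stricter filter, 48 with only the groups compared and 131 to 203 on leaving out 1 library. The 135 at 6 months were 10 without a filter, 44 with the stricter filter, 53 with DESeq2, 205 without the shallow libraries, 66 with only the groups compared and 74 to 171 on leaving out 1 library. The 36 at 9 months were 3 without a filter, 8 with the stricter filter, 14 with DESeq2, 19 with only the groups compared and 6 to 43 on leaving out 1 library. The stricter filter tests fewer genes by construction.

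The 3 calls of GFP by age were 8 with DESeq2 size factors, 0 with the stricter filter, 0 with DESeq2, 17 without the shallow libraries and 0 to 6 on leaving out 1 library. The 30 over age in GFP+ cells were 56 without a filter, 11 with the stricter filter, 0 with DESeq2, 11 with only the groups compared and 13 to 48 on leaving out 1 library (replicate 3 at 6 months and at 9 months). The 29 over age in GFP− cells were 60 with DESeq2 size factors, 5 without a filter, 2 with DESeq2, 3 with all 28 libraries, 96 without the shallow libraries, 53 with only the groups compared and 1 to 49 on leaving out 1 library.

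The 0 calls in salivary gland were 12 with DESeq2 size factors, 6 with all 28 libraries, 2 without the shallow libraries, 5 without ribosomal RNA rows and 0 to 18 on leaving out 1 library. The 140 between glands in GFP+ cells were 711 with DESeq2 size factors, 31 without a filter, 21 with the stricter filter, 514 with DESeq2, 286 with all 28 libraries and 31 to 142 on leaving out 1 library. The 138 in GFP− cells were 498 with DESeq2 size factors, 50 without a filter, 21 with the stricter filter, 370 with DESeq2, 208 without the shallow libraries and 32 to 203 on leaving out 1 library. The 0 calls of GFP by gland were 1 without the shallow libraries and 0 to 1 on leaving out 1 library (GFP− thyroid replicate 1).

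With the replicate number as a block, the calls were 188 for the mean, 45 at 3, 11 at 6 and 5 at 9 months, 19 and 2 over age in GFP+ and GFP− cells, and 71 between glands in GFP− cells. The pairing check gave 3 of 11 same-number thyroid pairs above 0.1, with a median of 0.044 against −0.017 for other pairs. In salivary gland 2 of 3 pairs were above 0.1 (0.083 to 0.187), with a median of 0.134 against −0.068. These values leave open whether the numbers pair the fractions.

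Of 100 called gene results named in the text, 65 kept their call without a filter, 75 of 96 with DESeq2, 90 with DESeq2 size factors, 89 of 99 without the shallow libraries, 72 with the replicate block, 91 of 99 with all 28 libraries and 99 without ribosomal RNA rows. On leaving out 1 library, 31 lost their call at least once. Signs changed for Cdkn1a in the mean GFP difference (0.0386 with DESeq2 size factors and 0.0638 with DESeq2, against −0.31) and for Klk1 in salivary gland (0.235 without GFP− replicate 3, −2.57 to 0.235 on leaving out 1 library).

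Of 83 list results, 24 kept their side with an estimated correlation and 59 did not, 39 kept it with fry, and 70 kept it without the shallow libraries. The direction changed for the stem and progenitor list in the mean (adjusted p = 0.43 without the shallow libraries), the CDK inhibitor list in the mean (0.989 with fry) and the immediate early list between 3 and 9 months (0.548 without the shallow libraries). At these depths, replicate numbers and spread, a 2-fold change was recovered for 37.3% of simulated genes in the mean contrast and for 0% at 3 months.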

Other observations

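The test of fibroblast label with age below was chosen only after the result was seen.

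Lists of immune cells and of dividing cells held few reads in these libraries. Over all 28 libraries the pan-leukocyte list held 49 reads, the macrophage list 111, the B cell list 11 and the neutrophil and mast cell list 10. The T and NK cell list held 215, with a pooled 280 CPM in GFP+ thyroid libraries at 9 months, where all 90 reads were of Thy1, also a fibroblast marker. The mitosis list held 390 reads with 0 members tested, and Mki67, a marker of dividing cells, had 3 reads in 1 library. Acinar genes in salivary gland summed to 151000 ± 65400 CPM in GFP− and 29900 ± 29700 CPM in GFP+ libraries (pooled 126000 and 56100, where replicate 3 held 79225 of the 92013 GFP+ reads), and duct genes to 16100 ± 11500 and 5330 ± 2910 CPM. Mitochondrial transcripts averaged 19.7% of the reads in salivary GFP+ and 10.1% in salivary GFP− libraries, against 3.11 to 5.66% in the thyroid groups.

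Y-linked genes had 18, 22 and 17 reads in GFP− and 1, 27 and 29 reads in GFP+ thyroid groups at 3, 6 and 9 months. In salivary gland they had 3 reads of 301336 in GFP− libraries (9.96 CPM) and 0 of 92013 in GFP+ libraries, where the limit was 32.6 CPM. Reads of both Xist and Y-linked genes were present in 3 of 3 GFP+ thyroid libraries at 9 months, 3 of 4 at 6 months and 1 of 4 at 3 months. In GFP− thyroid libraries this held for 1 of 4, 2 of 4 and 2 of 3 at 3, 6 and 9 months, and in salivary libraries for 2 of 3 GFP− and 0 of 3 GFP+.

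The smaller fibroblast median at 9 than at 3 months raised the hypothesis that fibroblasts may lose label with age. The fibroblast list gave an adjusted p of 0.73 for the difference between 9 and 3 months with an estimated correlation, so this could not be told. Pooled fibroblast levels were 4270 and 11500 CPM in GFP− and 21700 and 24500 CPM in GFP+ libraries at these ages.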
